A study of Mus musculus with 69 samples.

How the data were processed

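Gene expression was measured by 3′ mRNA sequencing in 69 mouse libraries from 3 experiments, which were analysed separately. Per the labels, RNA was isolated with a column microprep kit and libraries were made with the QuantSeq 3′ forward kit, in which reads start near the polyadenylated end, so counts need no correction for gene length. The labels describe the RNA of all 69 libraries as nuclear RNA from microglia, while 45 of them are also labelled hippocampus, and they were treated here as hippocampus. The authors deposited a table of raw counts per gene for each experiment, with whole numbers and no scaling. Per the submitters' processing notes, the genome builds were GRCm38 and mm10 and DESeq2 1.38.3 was used. The aligner, the counting program and the annotation release are not given in the sources used here. Gene coordinates in the agonist and microglia tables matched GENCODE M21 in chromosome, start and end for 98.3% of 54409 shared identifiers. The inhibitor table lists gene symbols alone, 100 of which stand for several identifiers in the other tables.

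Samples were grouped from their labels by sex and treatment in the hippocampal experiments and by sex, genotype and treatment in the microglia experiment. All count columns were matched to a sample by its label. The agonist experiment held 28 libraries in 4 groups of 7, the microglia experiment 24 libraries in 8 groups of 3, and the inhibitor experiment 17 libraries in groups of 3, 3, 5 and 6. Total counts had medians of 16.6, 16.2 and 15.7 M per library. The labels do not name a separate animal or culture for each microglia library, and some libraries of a group may be technical replicates, so p-values measure only the spread between samples. No correction by molecular identifiers is given in the sources used here, so count floors cover counting error only. No paired analysis was possible for the hippocampal libraries because their numbers follow the order of the samples. Replicate numbers of the microglia were entered as a block in an alternative fit, since same-numbered libraries deviated together by a correlation above 0.1 in 3 of 12 pairs of the same sex and genotype, all 3 between female KO DMSO and female KO myelin, and in 6 of 72 other pairs. Among libraries of different numbers 1 of 24 and 0 of 144 did so.

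Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr on the groups, scaled by the trimmed mean of M values (TMM) and fitted with 1 mean per group and robust quasi-likelihood dispersions in edgeR. The common biological coefficient of variation was 0.132 in the agonist, 0.0506 in the microglia and 0.179 in the inhibitor experiment. Each comparison was a 2-sided contrast of that fit, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Interactions were contrasts of differences. Standard errors were taken from the fold change and its F statistic, and they can be too small for very large changes. Group means with their SD are CPM with TMM scaling. Levels of single libraries, ranges over libraries, the CPM gained by oligodendrocyte genes and the plots of libraries are CPM without it. A gene with all libraries of a group at 3 counts or fewer was not given a fold change. The spread of fold changes between sexes was described with Pearson's r across genes, which are not independent replicates, so no p-value was attached.

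A set of 27 gene lists was tested with camera on voom values at a preset inter-gene correlation of 0.01, adjusted over all lists and comparisons of an experiment. The lists covered interferon response, NF-kB and cytokines, disease-associated and homeostatic microglia, cholesterol biosynthesis, LXR targets, lysosome, complement, MHC classes I and II, endosomal TLR signalling, cell cycle, immediate early genes, oxidative stress, unfolded protein response, X-linked and Y-linked genes. They also covered oligodendrocytes and their precursors, neurons, astrocytes, endothelium, pericytes with smooth muscle and fibroblasts, choroid plexus, peripheral immune cells, border-associated macrophages and erythroid cells. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance 1 way, were run beside it. Of 634 list tests, camera at the preset correlation called 276, and 53 of these held with an estimated correlation. Another 5 lists were written after the data had been seen, for glucocorticoid response, circadian clock output, heat shock, mitochondrially encoded genes and pituitary hormones.

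The comparisons, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule named 12 genes everywhere (among them Tlr7, Xist, Ddx3y, Irf7, Ifit3, Isg15, Cxcl10, Apoe, Trem2, Mbp and Abca1). It also named, in each comparison, up to 8 called genes in each direction by fold change among those of at least 4 CPM, with non-overlapping groups and a symbol that is not a predicted model, and the 3 members of each list with the smallest p. Fewer are printed where comparisons repeat each other, and some genes that the rule names are not reported here. The fixed alternatives were DESeq2 with its own scaling and filtering, relative log expression scaling in edgeR, no low-count filter, a filter at a mean of 5 CPM, limma with quality weights, a fit of only the groups compared, the replicate block in microglia, age as a covariate or only males of 1 age in the inhibitor experiment, and leaving out each library in turn. Covariates for Ttr, Pdgfra and the mitochondrial share, and fits without selected libraries, were added after the data had been seen. The SE of a list median with a covariate came from a linear fit of log2 CPM, by drawing the residuals of whole libraries 2000 times, with the inhibitor genes turned to their direction of change.

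Every comparison was also repeated on other splits of its libraries into groups of the same sizes, all of them where there were at most 100 and 100 drawn with a fixed seed otherwise. For interactions, the modifying factor was permuted within each treatment. Libraries were checked for mismatched sex, for duplicates and for single values far from their group by Dixon's test. The fits were tested on simulated data with 50 genes changed at each of 4 sizes, with the group sizes and the spread of single genes in the data. Each gene was drawn independently around a common mean over all groups. Structure shared by libraries was thus not simulated, and false calls may be more frequent in the data. In the male gardiquimod comparison, run on 17218 simulated genes, 26% of genes changed 1.25-fold were recovered, 56% at 1.5-fold and 96% at 2-fold, with 4 false calls. In the male WT myelin comparison, run on 14468 simulated genes, recovery was 40% at 1.25-fold and 92% at 3-fold. In the male inhibitor comparison, run on 17128 simulated genes, it was 0% at 1.25-fold, 58% at 2-fold and 82% at 3-fold, and the sex difference of that response recovered 30% at 2-fold and 60% at 3-fold. No recovered gene had the wrong sign. Sequence reads were not analysed here.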

Results

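To examine how Toll-like receptor 7 (TLR7), an endosomal sensor of single-stranded RNA, acts in brains and microglia of each sex, gene-level counts of 3′ mRNA libraries were compared in 3 mouse experiments. In the agonist experiment, hippocampi of wild-type (WT) mice given saline or gardiquimod, a TLR7 agonist, were measured in males and females with n = 7 libraries in each of 4 groups. In the microglia experiment, primary microglia from postnatal WT and Tlr7 knockout (KO) pups of each sex received DMSO or purified myelin, with n = 3 libraries in each of 8 groups. In the inhibitor experiment, hippocampi of mice labelled PSUK, a genotype the labels do not describe further, came from 3 female controls, 3 male controls, 5 females and 6 males given a TLR7 inhibitor that the labels do not name. Total counts were 14.3 to 23.5 M per library in the agonist experiment, 15.3 to 21.3 M in the microglia experiment and 14.4 to 21.03 M in the inhibitor experiment. After low counts were filtered, 17218, 14468 and 17128 genes were tested. Fold changes are log2 values with their standard error (SE), levels are mean CPM (counts scaled to a common library total) with the standard deviation (SD), and adjusted p-values come from edgeR unless another tool is named. The libraries compared differ in more than treatment, since agonist males were 12.12 months old and females 9.6 months, and PSUK mice were 5.5, 6.06 or 6.85 months old, where 1 age carries no unit and was read as months.

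Tlr7 (ENSMUSG00000044583, protein coding, GRCm38 chromosome X, 167304929 to 167330558, minus strand) was examined first. In DMSO cultures it stood at 186 ± 5.90 CPM in male WT and 192 ± 4.999 CPM in female WT microglia (n = 3 each). In KO microglia it was 2.02 ± 0.511 CPM in males and 2.11 ± 0.127 CPM in females with DMSO, and 1.57 ± 0.284 and 2.27 ± 0.607 CPM with myelin. Tlr7 was therefore lower in KO than in WT in every culture condition, with fold changes of -6.53 and -6.50 in male and female DMSO cultures and -6.79 and -6.24 with myelin. No SE is given for these 4 values, since one taken from the F statistic understates the spread of the low KO levels above. Tlr7 did not differ between WT males and females, with a female-to-male change of 0.04 ± 0.05 with DMSO (adjusted p = 0.712) and -0.03 ± 0.05 with myelin (adjusted p = 0.844). In hippocampus it was low, with means of 2.68 to 3.29 CPM in the agonist groups. Xist, the noncoding RNA of the inactive X chromosome, and Ddx3y, a Y-linked helicase gene, matched the labelled sex in all 3 experiments. Xist averaged 595 ± 179 CPM in saline females against 0.0849 ± 0.0922 CPM in saline males, and 435 ± 26.9 CPM in female WT DMSO microglia. Small traces of the other sex were present in KO cultures, with Xist at 1.43 ± 0.516 CPM in male KO DMSO microglia and Ddx3y at 0.358 ± 0.214 CPM in female KO DMSO microglia. Of the male inhibitor libraries, replicates 1 and 2 also held Xist, at 11.1 and 2.90 CPM without TMM scaling, and the group averaged 2.48 ± 4.42 CPM with it.

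To determine what TLR7 activation does in the hippocampus, gardiquimod was compared with saline in each sex and averaged over both. Interferon-stimulated genes rose in both sexes. Irf7 (ENSMUSG00000025498, GRCm38 chromosome 7, 141262706 to 141266481, minus strand), a transcription factor that amplifies type I interferon signalling, went from 2.58 ± 0.904 to 8.20 ± 3.11 CPM in males and from 2.99 ± 1.381 to 9.13 ± 2.09 CPM in females (n = 7 each). Averaged over the sexes, Irf7 rose by 1.64 ± 0.19 (adjusted p = 1.77e-05), and Ifi27l2a, an interferon-induced mitochondrial protein gene, by 2.04 ± 0.27. The antiviral genes Bst2, Ifit1, Lgals3bp, Rtp4, Oasl2, Ifit3 and Isg15 rose by 1.21, 1.17, 1.03, 0.996, 0.98, 0.95 and 0.91. Of the genes that present antigen on MHC class I, B2m rose by 0.50 ± 0.05 (adjusted p = 1.45e-06), H2-T23 by 0.60 ± 0.09 and H2-D1 by 0.58 ± 0.08. Among microglial genes, the glucan receptor gene Clec7a rose by 0.85 ± 0.18, Cd52, a leukocyte surface antigen gene, by 0.71 ± 0.15, and Ctss, a lysosomal protease gene, by 0.21 ± 0.05. The chemokine gene Cxcl10 was 1.01 ± 0.31 and did not pass (adjusted p = 0.411). Apoe was at 0.00 ± 0.07, Trem2 at 0.05 ± 0.05, Abca1 at -0.06 ± 0.07 and Mbp at -0.01 ± 0.09, none of them called, and Tlr7 itself was -0.10 ± 0.12. The average called 37 genes, all of them higher.

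Within males, 38 genes were called, 29 higher and 9 lower. Irf7 rose by 1.67 ± 0.27 (adjusted p = 0.00815), Ifi27l2a by 2.22 ± 0.39 (adjusted p = 0.0146), Rtp4 by 1.14 ± 0.20 (adjusted p = 0.00815) and B2m by 0.55 ± 0.08 (adjusted p = 4.24e-04). H2-Eb1, an MHC class II chain gene, rose by 1.33 ± 0.28, Col6a1, a collagen chain gene, by 0.72 ± 0.15, and Gbp3, a guanylate-binding protein gene, by 0.78 ± 0.15. The synaptic scaffold gene Homer1 fell, at -0.38 ± 0.07 (adjusted p = 0.00815), as did the somatostatin receptor gene Sstr4, at -0.51 ± 0.11. Within females, the 4 called genes were Irf7 at 1.60 ± 0.26 (adjusted p = 0.0121), Bst2 at 1.20 ± 0.22, H2-D1 at 0.59 ± 0.11 and B2m at 0.44 ± 0.08, all higher. All 4 genes called in females were also called in males, against 0.0067 for independent sets. The list of type I interferon response genes, 51 of which were tested, had 11 higher in males, 2 higher in females and 26 higher on average, and 44, 31 and 48 when adjusted over the list alone. Its median was 0.78 in males and 0.52 in females, and it kept its call with an estimated correlation (adjusted p = 0.0448, 0.0349 and 8.20e-04). The MHC class I list had 6 of 17 genes higher on average (14 adjusted over the list alone, adjusted p = 0.00173 with an estimated correlation). The male count moved from 7 without saline replicate 1 to 329 without saline replicate 3, and to 3 with the level of Ttr, a choroid plexus gene, as a covariate. With that covariate 13 of 32 named values were weaker. Over 22 alternative fits of the male comparison, Irf7 was 1.54 to 1.79 and B2m 0.51 to 0.58, called in each. Ifi27l2a was 2.05 to 2.41, called in 20. Homer1 was also called in 20, Gbp3 in 18, Col6a1 in 14 and Sstr4 in 11. Rtp4 was called in 21 of 21 fits and H2-Eb1 in 9 of 21. Ttr itself was higher with gardiquimod by 1.39 ± 0.96 in males and 0.79 ± 0.95 in females, not called. The female calls ended without gardiquimod replicate 2 or without saline replicate 1, 2, 5 or 7, each of which left 0 genes in edgeR, where DESeq2 on all libraries called 14 and 1044 genes had an unadjusted p under 0.05. Chance alone gives about 5% of the 17218 genes tested, and the 1044 genes are little above that share.

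**Figure D1:**
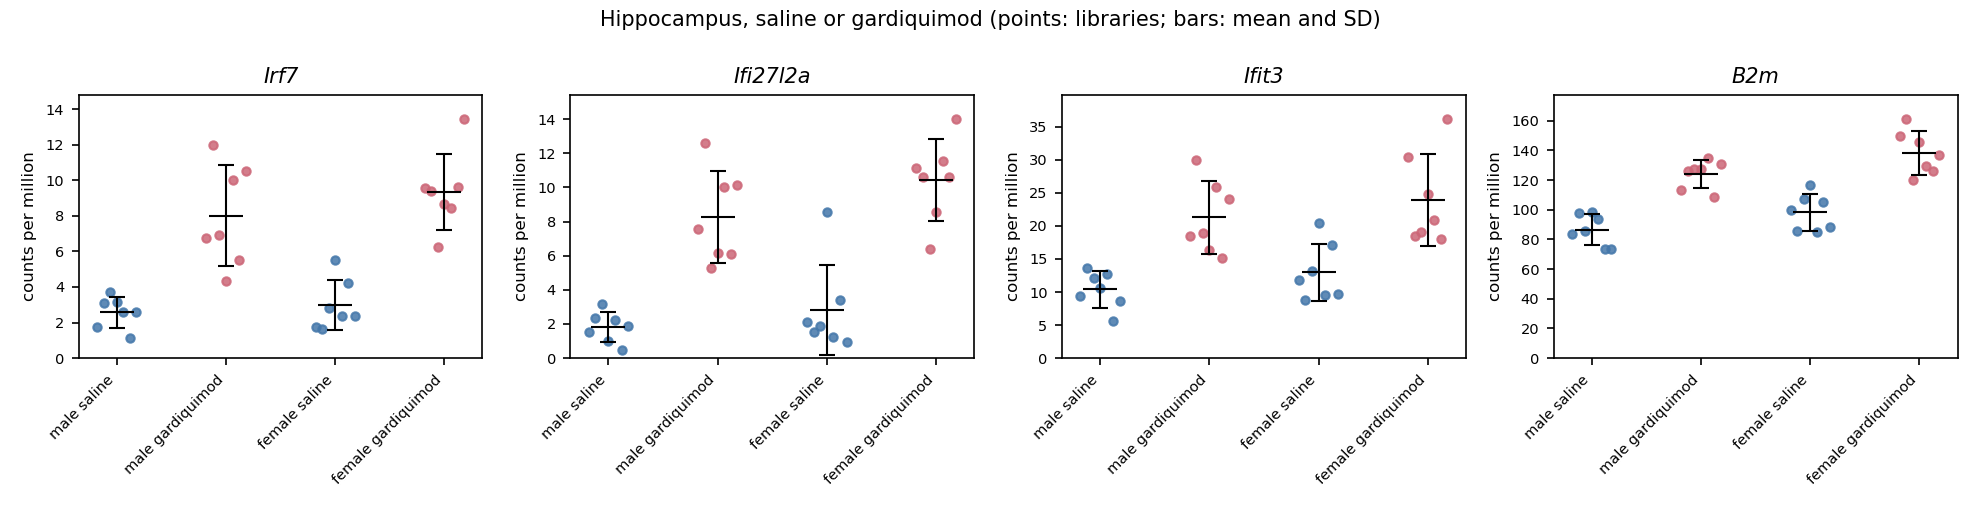
Each point is 1 hippocampal library (n = 7 in each of 4 groups of sex and treatment), with CPM on a linear y axis and black bars for the mean and SD. Irf7 ran from 4.36 to 12 CPM in gardiquimod males and from 6.27 to 13.5 CPM in gardiquimod females, above the ranges of 1.12 to 3.70 and 1.66 to 5.50 CPM in saline males and females, and B2m likewise did not overlap within either sex.

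A difference between the sexes in the gardiquimod response was tested as an interaction. Col6a1 was the 1 gene called, with a response lower in females than in males, at -1.26 ± 0.20 (adjusted p = 0.0144). The difference was -0.07 ± 0.37 for Irf7 (adjusted p = 0.949), -0.23 ± 0.31 for Ifit3 and 0.20 ± 0.35 for Isg15. Mbp, the myelin basic protein gene, was 0.23 ± 0.13 in males and -0.24 ± 0.13 in females, a difference of -0.46 ± 0.19 that did not pass (adjusted p = 0.235). Across genes the male and female responses had a Pearson's r of -0.0414, and genes are not independent replicates. The interferon response list had a median of -0.17 in the interaction (adjusted p = 0.765 with an estimated correlation). The count was 153 with DESeq2 and 35 without female gardiquimod replicate 5, so genes other than Col6a1 depended on the tool or on single libraries.

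Saline females and males differed in 74 genes, 58 of them higher in females. Beyond Xist and the X-linked genes Kdm6a (0.55 ± 0.07), Eif2s3x (0.54 ± 0.05) and Ddx3x (0.45 ± 0.05), females had higher Plin4, a lipid-droplet coat gene, by 2.02 ± 0.32 (adjusted p = 0.00150), Plekhf1, an endosomal phosphoinositide-binding gene, by 1.24 ± 0.18, and Tsc22d3, a glucocorticoid-induced regulator, by 1.01 ± 0.11 (adjusted p = 3.32e-07). Col6a1 was higher by 0.86 ± 0.15 and Rin2, a Rab5 regulator gene, by 0.69 ± 0.11. Cldn5, an endothelial tight-junction gene, was lower in females, at -0.57 ± 0.11, and so was Hrk, a BH3-only apoptosis gene, at -0.29 ± 0.07. Irf7 (0.22 ± 0.29), Mbp (0.20 ± 0.13) and Tlr7 (0.20 ± 0.17) did not differ. Sex and age changed together here, and the count fell to 47 without male saline replicate 1.

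To establish how microglia respond to myelin, myelin was compared with DMSO in male WT, female WT, male KO and female KO cultures, and values are given in that order. Sterol synthesis genes fell. Cyp51, a lanosterol demethylase gene, changed by -3.27, -3.79, -3.55 and -3.61 (SE 0.06, n = 3 against 3). Idi1, an isoprenoid enzyme gene, changed by -3.24, -4.23, -3.85 and -4.16. The cholesterol efflux transporter gene Abca1 rose by 2.28 ± 0.09, 2.51 ± 0.09, 2.56 ± 0.09 and 2.54 ± 0.09, and Abcg1 rose by 1.68, 1.65, 1.74 and 1.73. Plin2, a lipid-droplet coat gene, rose by 1.64, 1.63, 1.67 and 1.70 (SE 0.03), and Apoe fell by small amounts, -0.21, -0.30, -0.24 and -0.24 (SE 0.02). Of 25 cholesterol biosynthesis genes tested, 25, 24, 24 and 25 were lower, with medians of -2.15, -2.33, -2.26 and -2.11. Of 24 targets of the sterol-sensing LXR receptors, 11, 12, 12 and 10 were higher and 9, 8, 9 and 8 lower.

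Identity and inflammatory genes changed in all 4 cultures as well. The fractalkine receptor gene Cx3cr1 changed by -6.41 ± 0.16, -5.69 ± 0.15, -5.47 ± 0.16 and -6.17 ± 0.17, the growth factor receptor gene Csf1r, at -0.65, -0.67, -0.68 and -0.77, and Trem2, a lipid receptor gene, at -0.13, -0.23, -0.20 and -0.21. The chemokine gene Ccl5 rose by 5.59 ± 0.30, 5.21 ± 0.29, 5.02 ± 0.36 and 4.88 ± 0.30. Il1a, a proinflammatory cytokine gene, rose by 1.79, 1.78, 1.384 and 1.43, and Il1rn, which encodes an antagonist of its receptor, by 1.41, 1.27, 1.19 and 1.35. Lysosomal genes such as Psap (0.51, 0.47, 0.48 and 0.50) and Ctsz (0.68, 0.64, 0.57 and 0.59) rose, with 26, 27, 25 and 24 of 41 lysosome and phagocytosis genes higher and 5, 9, 10 and 10 lower. Top2a, a topoisomerase of dividing cells, fell, at -1.48, -1.46, -1.12 and -1.26, and 29, 30, 26 and 27 of 30 cell cycle genes were lower. The iron exporter gene Slc40a1 fell, at -1.91, -2.27, -2.12 and -2.13, the MHC class II chaperone gene Cd74, at -1.36, -1.33, -1.21 and -1.22, and the complement gene C1qc, at -0.53, -0.62, -0.26 and -0.37. Of 31 NF-kB and cytokine response genes, 20, 20, 14 and 16 were higher and 2, 2, 4 and 7 lower, of 22 homeostatic microglia genes, 12, 12, 10 and 13 were lower and 8, 7, 5 and 4 higher, and of 17 immediate early genes, 7, 9, 11 and 9 were lower. The MHC class II list (8 tested), the complement list (11) and the unfolded protein response list (16) had genes called in both directions, and none of these 6 lists was called with an estimated correlation (smallest adjusted p = 0.0787, for NF-kB in male WT).

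Many interferon-stimulated genes rose with myelin, with the fewest called in male KO cultures. Neither Irf7 nor, with an estimated correlation, the list was called for a genotype difference of the response (adjusted p = 0.476 and 0.656 in males). Ifi27l2a went the other way in each culture. Its means went from 36.8 to 22.1, from 40.9 to 19.8, from 15.05 to 6.45 and from 17.1 to 13.02 CPM without TMM scaling. Irf7 rose by 1.60 ± 0.34 (adjusted p = 9.99e-04), 1.13 ± 0.34 (adjusted p = 0.0130) and 1.93 ± 0.38 (adjusted p = 5.19e-04), while in male KO it was 0.64 ± 0.40 (adjusted p = 0.233). Ifit3 rose by 2.21 ± 0.44, 1.63 ± 0.45 and 2.81 ± 0.55 in the same cultures and was 0.98 ± 0.59 in male KO (adjusted p = 0.220). Of 54 interferon response genes, 45, 28, 12 and 49 were higher in the 4 cultures, and 46, 33, 9 and 49 when adjusted over the list alone, with medians of 0.84, 0.61, 0.38 and 1.17. With an estimated correlation this list was not called (adjusted p = 0.330, 0.444, 0.577 and 0.332), while cholesterol biosynthesis was (2.68e-06 or less) and so was cell cycle (0.00894 or less). In all, 5691, 5840, 5530 and 5959 genes were called, with 2887, 2794, 2602 and 3006 of them higher. Over all genes tested, 49.3, 49.3, 46.4 and 47.6% had groups that did not overlap, where chance gives 10% for 3 against 3. Across genes the myelin fold changes of male and female WT microglia had a Pearson's r of 0.790, and 2243 genes were called higher and 2356 lower in both, against 558 and 590 for independent sets.

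**Figure D2:**
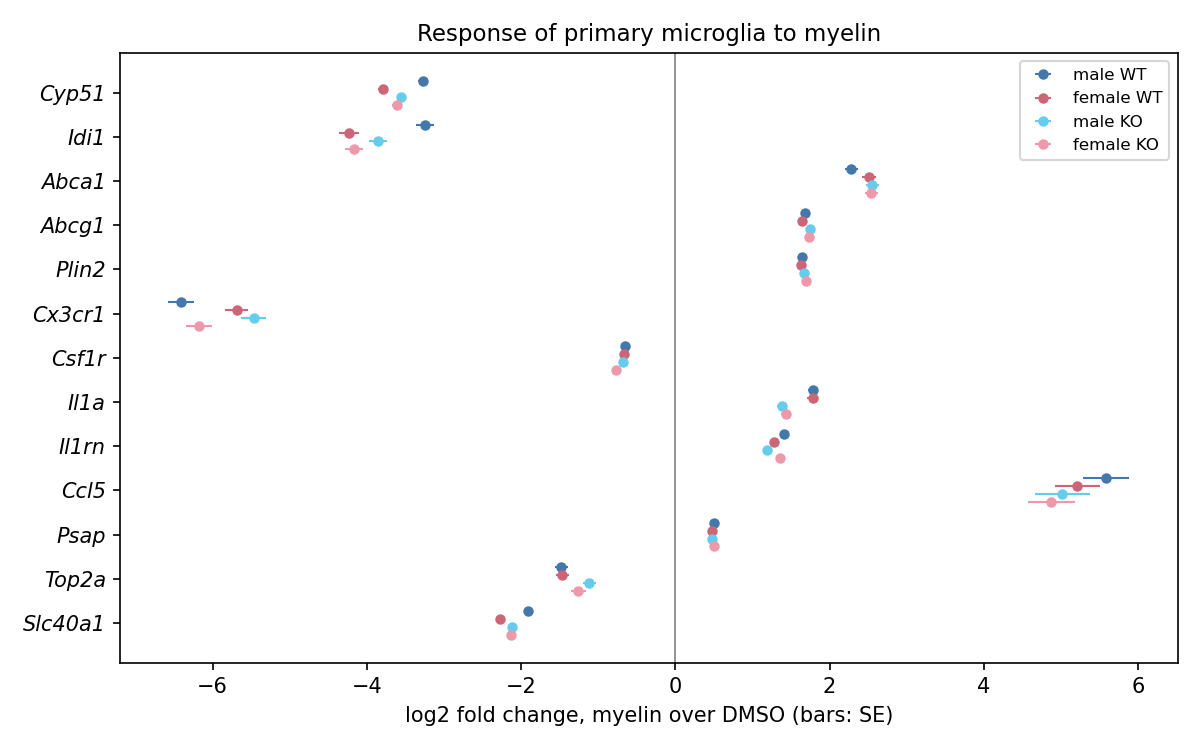
The x axis gives the log2 fold change of myelin over DMSO with its SE for 13 genes on the y axis, with 1 coloured point for each of the 4 cultures (n = 3 against 3 libraries). Cyp51, Idi1, Csf1r and Cx3cr1 lay below 0 and Abca1, Abcg1, Plin2, Il1a and Ccl5 above 0 in all 4 cultures.

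Transcripts of oligodendrocytes, the cells that make myelin, were also measured. Mobp, a structural myelin protein gene, rose by 5.09 ± 0.27, 4.85 ± 0.25, 5.82 ± 0.29 and 6.11 ± 0.28, and Mbp rose by 1.80, 1.77, 1.77 and 2.26 (SE 0.15). Of 25 myelin and oligodendrocyte genes tested, 3, 3, 2 and 3 were higher and 5, 9, 9 and 9 lower. Of 11 oligodendrocyte precursor genes, 2 were higher in each culture and 7, 5, 5 and 7 lower, with Bcas1, a gene of newly formed oligodendrocytes, higher by 1.90, 2.02, 2.37 and 2.77.

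To ask what loss of TLR7 changes, KO was compared with WT microglia, in the order male DMSO, female DMSO, male myelin and female myelin. Besides Tlr7, Wdfy1 (GRCm38 chromosome 1, 79702262 to 79776143, minus strand), an adaptor gene of endosomal receptor signalling, changed in all 4 comparisons and was higher in KO by 2.0001 ± 0.06, 1.88 ± 0.05, 1.78 ± 0.05 and 1.84 ± 0.05 (n = 3 against 3). Mid1 (GRCm38 chromosome X, 169685199 to 170005736, plus strand), a ubiquitin ligase gene near Tlr7, was lower, at -2.47, -3.33, -3.43 and -3.47. The complement inhibitor gene Cd59a was higher by 1.64, 1.381, 1.52 and 1.52, Mamdc2, a proteoglycan gene, by 1.33, 1.32, 1.63 and 1.75, and the neuropeptide gene Npy by 2.05, 1.51, 1.377 and 1.30. Lower in KO were the TAM receptor gene Axl, at -0.88, -0.62, -1.05 and -0.67 (SE 0.04), and Pf4, a platelet-type chemokine gene, at -0.81, -0.68, -0.68 and -0.51. Ctsd, a lysosomal protease gene, was higher by 0.55, 0.22, 0.43 and 0.19, and Trem2 by 0.34, 0.09, 0.27 and 0.11. Apoe differed little, at 0.07, 0.00, 0.05 and 0.06 (SE 0.02), and Abca1 was lower in male DMSO cultures, at -0.44 ± 0.09 (adjusted p = 0.00148). The 4 comparisons called 3027, 1721, 2987 and 1053 genes, of which 1679, 784, 1457 and 550 were higher. Over all genes tested, 35.2, 26.3, 34.5 and 22.6% had groups that did not overlap.

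Interferon-stimulated genes were lower in KO, with 1 of them called in female myelin cultures. Ttr and Pdgfra, markers of choroid plexus and precursor cells, moved with genotype. With their levels as covariates the genes called in the other 3 comparisons fell to 0, 1 and 0. The list medians there went from -0.78 to -0.79, from -0.80 to -0.76 and from -1.23 to -1.27, while the median SE widened. In male myelin cultures Irf7 was lower, at -2.01 ± 0.35 (adjusted p = 4.19e-04), Ifit3, at -2.50 ± 0.45 (adjusted p = 5.82e-04), Isg15, at -1.96 ± 0.39 and Cxcl10, at -1.97 ± 0.45. In female DMSO cultures Irf7 was lower, at -1.37 ± 0.39 (adjusted p = 0.0309), and the antiviral genes Oas2 and Ifitm3, at -1.62 ± 0.37 and -1.33 ± 0.26. In male DMSO cultures Irf7 was -1.05 ± 0.39 (adjusted p = 0.0680). In female myelin cultures Irf7 was -0.56 ± 0.33 (adjusted p = 0.406) and Ifit3 -0.46 ± 0.41, neither called. Of 54 interferon response genes, 26, 26, 53 and 1 were lower and Ifi27 alone was higher, by 0.44, 0.22, 0.57 and 0.29. Adjusted over the list alone, 43, 51, 53 and 1 were lower, and the list medians were -0.78, -0.80, -1.23 and -0.37. With an estimated correlation the list was not called (adjusted p = 0.268, 0.193, 0.0979 and 0.315). The chemokine genes Ccl7 and Ccl12 were called lower in KO in all 4 comparisons, at -1.31, -1.88, -1.377 and -1.21 for Ccl7 and -0.97, -1.58, -1.84 and -1.07 for Ccl12. Arg1, an arginase gene, was lower, at -0.98 ± 0.03 in female myelin cultures.

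Other gene lists were compared between KO and WT. Of 33 disease-associated microglia genes, 23, 17, 18 and 19 were higher in KO and 4, 3, 7 and 3 lower, a call that held with an estimated correlation in male DMSO, female DMSO and female myelin cultures (adjusted p = 0.00419, 0.0332 and 0.0159) and not in male myelin cultures (0.0720). Of 41 lysosome and phagocytosis genes, 32, 17, 32 and 11 were higher (adjusted p = 0.0132, 0.316, 0.0361 and 0.426 with an estimated correlation). Of 25 cholesterol biosynthesis genes, 13 and 10 were higher with DMSO (adjusted p = 0.00987 and 0.00350 with an estimated correlation), among them Msmo1, a sterol oxidase gene, by 0.37 and 0.27, and with myelin 2 were higher in each sex. Of 30 cell cycle genes, 17, 11, 1 and 1 were lower (adjusted p = 0.0115, 0.00225, 0.967 and 0.325 with an estimated correlation), with Mcm5, a replication helicase gene, at -0.54 and -0.59 with DMSO. Of 17 oxidative stress genes, 10, 12, 5 and 8 were higher (0.165, 0.0159, 0.690 and 0.0405), including Sqstm1, an autophagy receptor gene, by 0.37, 0.32, 0.17 and 0.21. Of 23 endosomal TLR signalling genes, 7, 7, 10 and 5 were lower, Tlr7 among them (0.352, 0.0833, 0.0261 and 0.0132), and Tlr8, its neighbouring sensor gene, was at -0.19, -0.40, -0.24 and -0.37. The p-values of this list include the deleted gene itself, so they cannot by themselves show a shift of its other members.

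Some markers of choroid plexus and glia were lower in male KO. Ttr (GRCm38 chromosome 18, 20665250 to 20674324, plus strand), a transthyretin gene of choroid plexus, was lower in male KO, at -4.10 ± 1.09 with DMSO (adjusted p = 0.0117) and -4.06 ± 1.09 with myelin (adjusted p = 0.0126), and the 15 choroid plexus genes had medians of -3.35, 0.88, -3.37 and 0.80. In female KO DMSO replicates 1, 2 and 3 Ttr was 512, 55.7 and 42.4 CPM against 80.7 to 148.8 CPM in female WT, so a female rise rests on replicate 1. The glial receptor phosphatase gene Ptprz1 was lower in male KO, at -1.08 and -1.19, and higher in female KO with DMSO by 0.44. With Ttr and Pdgfra levels as covariates the counts fell to 477, 872 and 329 in the male DMSO, female DMSO and male myelin comparisons, and Col8a1, Enpp2, Igfbp2, Vat1l, Sulf1 and Foxj1, called lower in male KO, reversed in at least 1 male comparison. Across genes the KO effects of males and females had a Pearson's r of 0.016 with DMSO and 0.073 with myelin, or 0.453 and 0.438 among genes of at least 5 CPM, and 484 genes were higher and 402 lower in both sexes with DMSO, against 91.0 and 87.3 for independent sets.

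**Figure D3:**
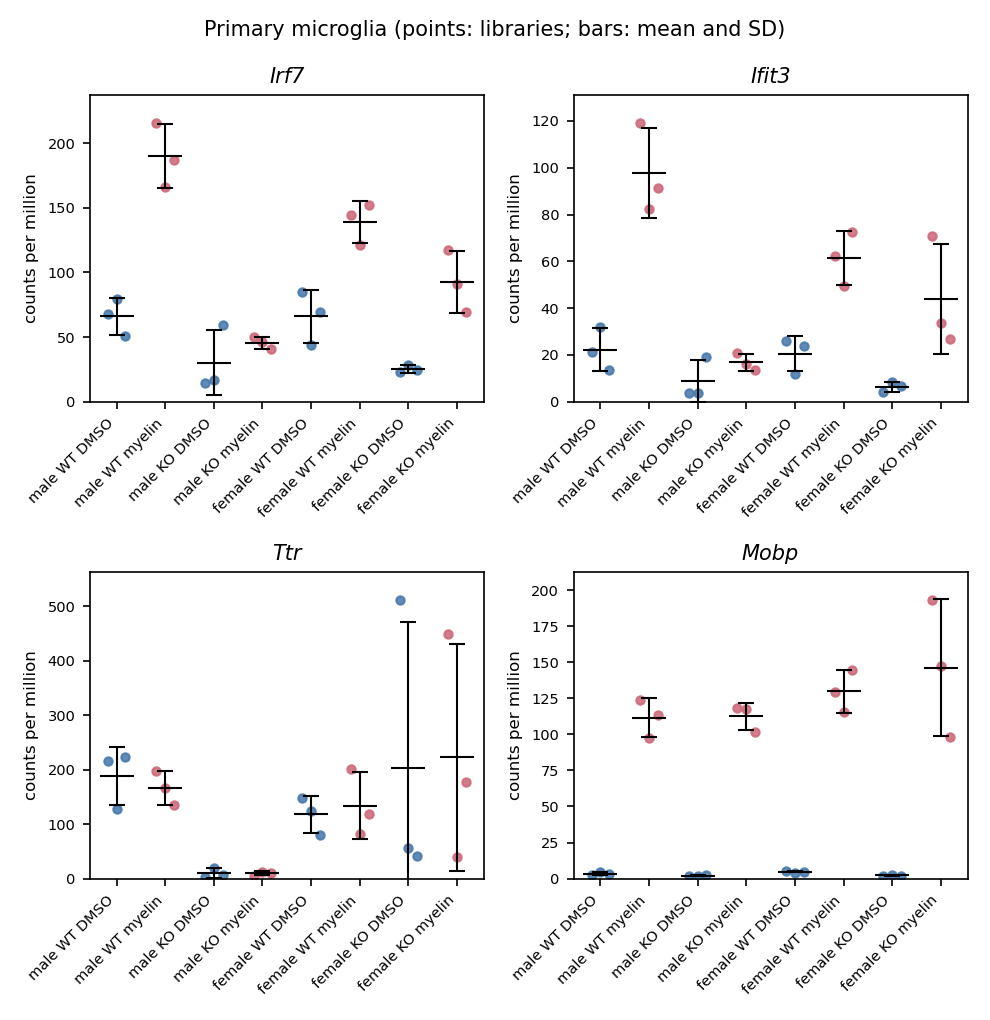
Each point is 1 microglia library (n = 3 in each of 8 groups of sex, genotype and treatment), with CPM on a linear y axis and black bars for the mean and SD. Irf7 reached 166.6 to 215.9 CPM in male WT myelin cultures against 40.5 to 50.01 CPM in male KO myelin cultures, and Ttr was 3.74 to 20.1 CPM in male KO DMSO cultures against 42.4 to 512 CPM in female KO DMSO cultures.

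Whether genotype altered the response to myelin was tested as an interaction in each sex. In males 371 genes were called, 114 with a higher response in KO and 257 with a lower one. Responses were compared as signed log2 fold changes, so a higher one is a smaller fall in a gene that falls with myelin. More and less are used in that sense here. Inhba, an activin subunit gene, responded less in KO, at -1.37 ± 0.26 (adjusted p = 4.93e-04), the prostaglandin synthase gene Ptges, at -1.15 ± 0.24, the lipopolysaccharide co-receptor gene Cd14, at -0.96 ± 0.07 (adjusted p = 1.30e-09) and the NF-kB inhibitor gene Tnfaip3, at -0.39 ± 0.06. Clec7a was lower, at -0.39 ± 0.04 and Gpnmb, a lysosomal glycoprotein gene, at -0.34 ± 0.04, and 10 of 33 disease-associated microglia genes responded less in KO against 1 more (adjusted p = 0.00894 with an estimated correlation). Uhrf1, a DNA methylation maintenance gene, had a log2 response higher in KO by 0.90 ± 0.18. So had 4 of 30 cell cycle genes, 9 adjusted over the list alone (adjusted p = 0.0145 with an estimated correlation). As most genes of that list fell with myelin, this is mainly a smaller fall in KO. Of the cholesterol biosynthesis genes, which fell with myelin, 6 fell further in KO. In females 133 genes were called, 65 higher and 68 lower. Cd83, a dendritic cell activation gene, responded more in KO by 0.65 ± 0.11 (adjusted p = 1.49e-04) and Gas6, the ligand gene of Axl, by 0.26 ± 0.04. The formyl peptide receptor gene Fpr1 responded less, at -0.83 ± 0.13 (adjusted p = 3.88e-05), Tlr2, at -0.74 ± 0.11, and Birc3, an apoptosis inhibitor gene, at -0.60 ± 0.10. C1qc, which fell with myelin in every culture, fell less in KO of both sexes, by 0.27 and 0.25. Irf7 was -0.96 ± 0.52 in males (adjusted p = 0.476) and 0.81 ± 0.51 in females (adjusted p = 0.679), and the medians of the interferon response list were -0.46 and 0.46 (adjusted p = 0.656 and 0.375 with an estimated correlation). The female count fell to 73 and 84 without WT myelin replicate 1 or 3, to 75 without WT DMSO replicate 1, and to 40 with Ttr and Pdgfra as covariates.

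To compare the sexes, female and male WT microglia were set against each other. With DMSO 536 genes differed, 283 higher in females. The X-linked genes Kdm6a and Eif2s3x were higher by 0.73 ± 0.07 and 0.69 ± 0.04, Trem2 by 0.13 ± 0.03 and Gpnmb by 0.18 ± 0.03, and 13 of 33 disease-associated microglia genes were higher in females (adjusted p = 0.0320 with an estimated correlation). Cst7, another gene of that list, was called lower in females, at -0.43 to -0.19 over 14 alternative fits. Glial and precursor genes were lower, with Ncan, a brain proteoglycan gene, at -1.16 ± 0.09 (adjusted p = 6.20e-10), Cacng4, a glutamate receptor subunit gene, at -1.30 ± 0.16, and Ptprz1 at -1.11 ± 0.13, and 7 of 11 oligodendrocyte precursor genes were lower (adjusted p = 0.00149 with an estimated correlation). With myelin 389 genes differed, 155 higher in females. Kcnn4, a potassium channel gene of microglia, was higher by 0.65 ± 0.08 (adjusted p = 1.56e-08), and Idi1 was lower, at -0.97 ± 0.19. Irf7 did not differ, at 0.04 ± 0.36 with DMSO and -0.44 ± 0.32 with myelin. With Ttr and Pdgfra as covariates the counts fell to 19 and 14, and Slc4a4 and Scd2, called lower in female DMSO cultures, reversed. The DMSO count was 281 to 337 without female replicate 2 or 3 or male replicate 1 or 2, and the myelin count 213 to 238 without female replicate 1 or 3 or male replicate 2.

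The sexes differed in the myelin response of 6 genes. In females Cyp51 fell further, at -0.52 ± 0.09 (adjusted p = 0.00642), as did Idi1, at -0.99 ± 0.21, called in 9 of 20 fits, and 3 of 25 cholesterol biosynthesis genes (adjusted p = 0.00736 with an estimated correlation), and likewise Slc40a1, at -0.36 ± 0.06 and Zfp36, an mRNA decay factor gene, at -0.29 ± 0.06. Cyp4f18, a fatty acid hydroxylase gene, was raised further in females by 1.248 ± 0.23 (adjusted p = 0.00642). The count was 3 without female WT myelin replicate 1 or male WT myelin replicate 1 or 2. The KO effect in myelin cultures differed between the sexes in 942 genes, 508 of them higher in females. Cd93, a phagocyte surface gene, was -0.98 ± 0.07 (adjusted p = 1.70e-16), Trem2 -0.16 ± 0.04 and Ctsd -0.24 ± 0.03, all with a lower KO effect in females, and 18 of 41 lysosome and phagocytosis genes shared that direction (adjusted p = 0.0428 with an estimated correlation). Socs3, a cytokine signalling inhibitor gene, was higher by 0.62 ± 0.09, Cxcl2, a neutrophil chemokine gene, by 1.28 ± 0.20 and Gbp2, an interferon-induced GTPase gene, by 1.02 ± 0.26. Irf7 and Ifit3 differed by 1.44 ± 0.48 (adjusted p = 0.0870) and 2.04 ± 0.61 (adjusted p = 0.0583), and 3 of 54 interferon response genes were called higher in females, 38 when adjusted over the list alone. The matrix genes Cyr61 and Sparc were higher by 2.77 ± 0.47 and 2.26 ± 0.45, and Ttr by 4.80 ± 1.36. With Ttr and Pdgfra as covariates 49 genes were called and Igfbp2, Atp1b1 and Wwc1 reversed, and without female KO myelin replicate 1 the count was 625.

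To ask what TLR7 inhibition does in the hippocampus of PSUK mice, inhibitor was compared with control in each sex. Tlr7 itself was 0.26 ± 0.37 in males and -0.13 ± 0.38 in females, not called in either. In males 18 genes were called, 6 higher and 12 lower. The chaperone genes Dnajb1 and Hspa1a fell, at -1.04 ± 0.13 (adjusted p = 0.00371) and -2.33 ± 0.39 (adjusted p = 0.0367), as did the kinase gene Sgk1 at -1.503 ± 0.27, the signalling inhibitor gene Errfi1 at -1.01 ± 0.16, the cell cycle inhibitor gene Cdkn1a at -1.07 ± 0.20 and the mTOR inhibitor gene Ddit4 at -0.83 ± 0.14 (n = 6 against 3). Nr2c2, an orphan nuclear receptor gene, rose by 0.70 ± 0.10 (adjusted p = 0.0196) and Lonrf3, a ubiquitin ligase gene, by 0.79 ± 0.14. In females 15 genes were called, 3 higher and 12 lower (n = 5 against 3). Nr2c2 fell, at -0.69 ± 0.10 (adjusted p = 0.0145), Lonrf3, at -0.93 ± 0.14, Zbtb20, a transcription repressor gene, at -0.74 ± 0.11 and Malat1, a nuclear noncoding RNA, at -0.76 ± 0.14, while Dio3, a thyroid hormone deiodinase gene, rose by 1.74 ± 0.29 (adjusted p = 0.0272). The male count was 1 without control replicate 3 or inhibitor replicate 2, 4 or 6, and the female count 0 in edgeR without control replicate 1 or 3, where DESeq2 on all libraries called 173 and 1982 genes had an unadjusted p under 0.05.

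Averaged over the sexes 2 genes were called, both lower, and the 1 named by the rule was Malat1 at -0.67 ± 0.10 (adjusted p = 0.0145). The other was 9530059O14Rik, a gene of unknown function below the level the naming rule asks for and named here after its values were seen, at -1.92 ± 0.24. No gene was called in the same direction in both sexes and 4 were called in opposite directions, and across genes the male and female responses had a Pearson's r of -0.395. The sex difference of the response was called for 413 genes, 125 with a higher response in females and 288 with a lower one. Hspa1a, Dusp5, a phosphatase gene induced by growth signals, and Cdkn1a were higher in females relative to males by 3.21 ± 0.60 (adjusted p = 0.0149), 2.02 ± 0.36 and 1.73 ± 0.30, and the interneuron peptide genes Npy and Sst by 1.45 ± 0.31 and 1.24 ± 0.31. Adcy1, a neuronal adenylyl cyclase gene, was lower, at -2.17 ± 0.36 (adjusted p = 0.0101), the isoprenyl transferase gene Ptar1, at -2.11 ± 0.33, the cystine transporter gene Slc7a11, at -1.95 ± 0.41 and Pdgfra, a precursor-cell receptor gene, at -0.60 ± 0.12. This count ran from 1 with the Ttr level as a covariate to 4732 with quality-weighted limma, and from 25 without female control replicate 3 to 2500 without female inhibitor replicate 3. With the Ttr level the median size over the 413 genes went from 1.02 to 1.03, while their median SE widened from 0.23 to 0.32.

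The interferon gene Irf7 and the myelin gene Mbp were not called with the inhibitor. Irf7 was -0.13 ± 0.49 in males (adjusted p = 0.899) and -0.53 ± 0.48 in females (adjusted p = 0.686), with group means of 2.52 and 2.30 CPM in male controls and treated males. Mbp was 0.32 ± 0.31 in males and -0.05 ± 0.32 in females. The medians of the 46 interferon response genes tested were 0.26 in males and -0.28 in females (adjusted p = 0.807 and 0.807 with an estimated correlation). Choroid plexus genes differed between groups without being called, with a median of 2.01 in females and -0.22 in males, and Ttr averaged 484 ± 806 CPM in female controls, 3999 ± 367 in treated females, 3247 ± 134 in male controls and 2077 ± 1665 in treated males. Female and male controls differed in 11 genes, among them Per3, a circadian clock gene, higher in females by 0.80 ± 0.13 (adjusted p = 0.0156), Nr2c2 by 0.66 ± 0.12, Kdm6a by 0.77 ± 0.11 and Eif2s3x by 0.77 ± 0.10, while Dnajb1 was lower, at -0.86 ± 0.16 (adjusted p = 0.0441). That count was 6 without male control replicate 2 or 3, 7 without female control replicate 3 and 23 without female control replicate 2.

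**Figure D4:**
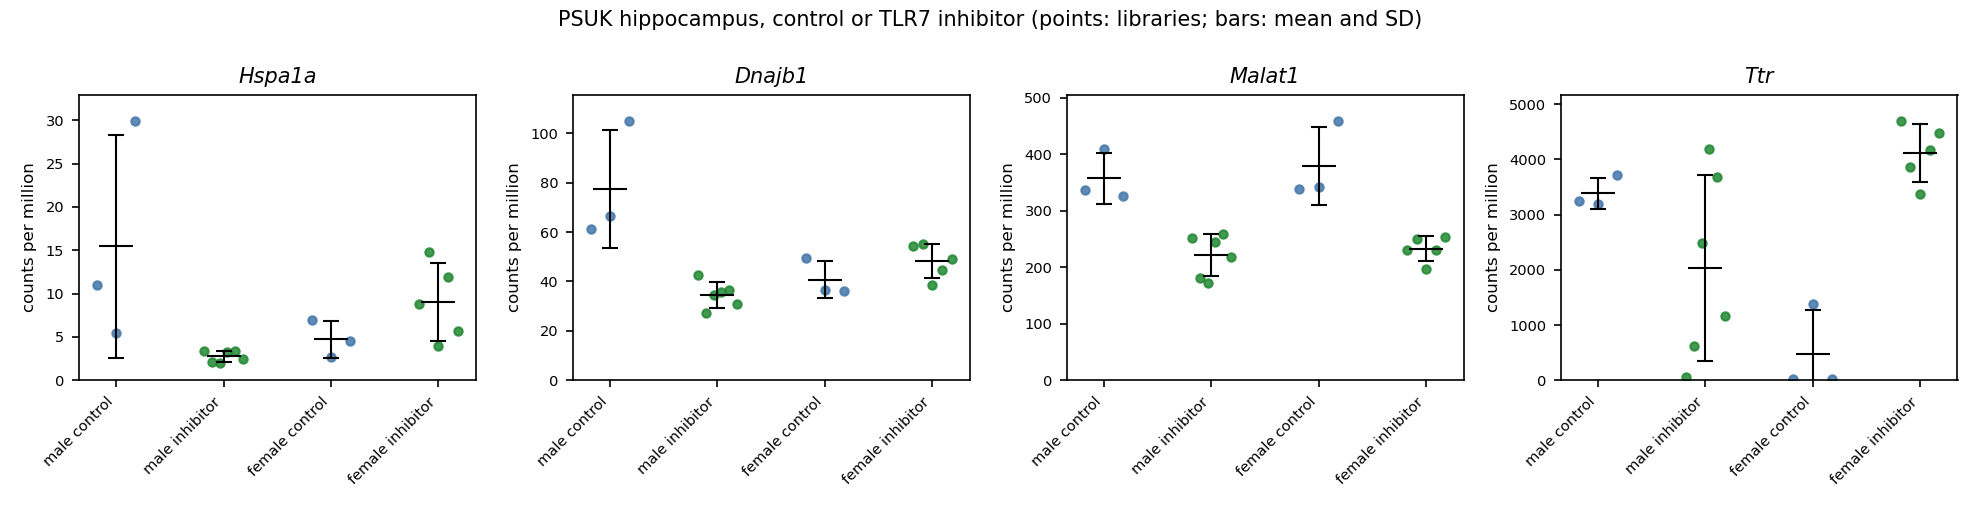
Each point is 1 PSUK hippocampal library (n = 3 male controls, 6 treated males, 3 female controls and 5 treated females), with CPM on a linear y axis and black bars for the mean and SD. Hspa1a ran from 5.41 to 29.9 CPM in male controls and from 2.02 to 3.401 CPM in treated males, and Malat1 was lower in treated than in control mice of each sex without overlap.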

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

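The tests on oligodendrocyte transcripts, and the SE of a list median against which covariate tests were judged, the 3rd spread tried, were chosen only after the results were seen, as were Wdfy1, Ide and Hspa1a among the measures searched for single deviating libraries.

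In microglia given myelin 4 oligodendrocyte-lineage genes, taken because they rose in every culture, were higher, while more genes of these lists fell than rose. Over DMSO, Mbp gained 265.5 to 367.3 CPM in the 4 cultures, Mobp 108.2 to 144.1 CPM, Cspg4 17.7 to 28.9 CPM and Bcas1 14.6 to 20.5 CPM. More oligodendrocyte-lineage cells in the treated cultures were argued against, since the precursor list had a median below 0 in each culture, the highest at -0.26. RNA brought in with the added myelin may account for the rise of these 4 genes, as the gain, a measure chosen after fold over DMSO had been tried, differed between cultures by 1.40-fold in the median over these 4 genes. The same idea judged by fold over DMSO gave a ratio of 1.62 and could not decide, because these genes were above the 2 CPM asked for in DMSO cultures, and expression of these genes by the microglia stays open and was not tested.

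Interferon-stimulated genes were lower in KO microglia where choroid plexus and precursor transcripts also differed. With Ttr and Pdgfra levels as covariates the list median went from -0.78 to -0.79 in male DMSO, from -0.80 to -0.76 in female DMSO and from -1.23 to -1.27 in male myelin cultures, 1.02, 0.949 and 1.04 of its size. The genes called lower went from 26 to 0, 26 to 1 and 53 to 0, because the median SE widened from 0.26 to 0.58, from 0.26 to 0.36 and from 0.23 to 0.58. In male myelin cultures the median cleared 50% of its size by 0.66 in edgeR and 0.87 in a linear fit of log2 CPM, against an SE of 0.61. This passed the SE asked for in both fits, though by under 2 SE. Both covariates were separated by genotype there, with Ttr at 135.3 to 197.5 CPM in WT and 5.50 to 12.6 CPM in KO. Pdgfra was at 13.3 to 17.7 and 6.78 to 7.66 CPM. The margin is therefore too small to tell genotype from other cells. With DMSO the verdict changed with the fit, at 0.40 and 0.67 against 0.57 in males and 0.36 and 0.31 against 0.34 in females, so genotype and the amount of other cells cannot be told apart there, and loss of TLR7 signalling, which the design names, stays open.

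The response of PSUK mice to the inhibitor differed between the sexes, with 413 genes called for the difference, a median size of 1.02 over them and 4 genes called in opposite directions. The mitochondrial share of the counts was argued against as the whole cause. With it as a covariate the sizes kept 0.871 of their value in the median over genes, the median SE narrowed from 0.23 to 0.17 and 411 of the 413 genes were among 1729 called. Without the 4 libraries under 6% mitochondrial counts, which also leaves fewer libraries, 24 of 64 named values were weaker. Age was argued against as well, with a median ratio of 1.02 and 399 of the 413 genes among 522 called. For choroid plexus carried along in dissection, the median ratio was 0.9996 with the Ttr level as a covariate. The list median cleared 50% of its size by 0.52 against its SE of 0.22. All calls save 1 ended, because the median SE of single genes widened from 0.23 to 0.32 while the median size went from 1.02 to 1.03. However, Ttr did not overlap between female controls (16.9 to 1386 CPM) and treated females (3370 to 4695 CPM), and the genes were chosen for this interaction. Choroid plexus and treatment therefore cannot be told apart in females, and choroid plexus stays open. A response to TLR7 inhibition that differs between sexes stays open and untested, as does a difference among controls, since over these genes, chosen for the interaction, females differed from males by a median size of 0.47 in controls (3 against 3) and 0.54 with inhibitor (5 against 6).

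The differences between groups in their response rest on tests of the interaction. Chance was taken as excluded where under 5% of the splits of the same libraries, the real one included, called at least as many genes. The sex difference of the gardiquimod response called 1 gene, reached by 4 of 100 splits, of which 1 called 78 genes. The sex difference of the genotype effect in myelin microglia called 942 genes against 267 in the highest other split, and the sex difference of the inhibitor response 413 against 5. For both, this excludes a chance division of the libraries into females and males. In microglia it says nothing about cultures or animals, since libraries of a group may be technical replicates and were exchanged singly. Neither genotype nor treatment was exchanged in these splits. Structure among single libraries is not excluded, since the inhibitor count ran from 25 to 2500 with 1 library left out. For the genotype difference of the myelin response, with 371 genes in males and 133 in females, and the sex difference of the myelin response, with 6 genes, 10 of 100 splits each called as many, the highest others 1568, 865 and 195. This decides nothing, because an uneven exchange of genotype or sex within a treatment turns the difference between genotypes or sexes itself into an interaction. No biological explanation of these differences was tested beyond the patterns weighed above.

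For the comparisons of groups, chance can be excluded by this rule for gardiquimod in females (4 genes, reached by 1 of 100 splits, highest other 2). The same holds for gardiquimod on average (37, 1 of 100, highest other 2) and for the inhibitor in males (18, 1 of 84, highest other 1). The rule was also met for gardiquimod in males (38, 3 of 100, highest other 629) and saline females against males (74, 2 of 100, highest other 313). It was met as well for the inhibitor on average (2, 3 of 100, highest other 3991). In these last 3 comparisons another split called far more genes than the real groups, so chance is not firmly excluded there. Chance could not be excluded for the inhibitor in females (15, reached by 5 of 56 splits, highest other 3655). The splits with 629, 313, 3991 and 3655 genes point to a structure of the samples other than their groups. The 10 splits of 3 against 3 libraries are too few for a decision. There, myelin called 5691, 5840, 5530 and 5959 genes in male WT, female WT, male KO and female KO cultures, and the highest other splits 0, 0, 0 and 117. KO against WT called 3027, 1721, 2987 and 1053 in male DMSO, female DMSO, male myelin and female myelin cultures, against 2, 0, 0 and 1, and females against males called 536 in WT DMSO, 389 in WT myelin and 11 in PSUK controls, against 0, 1 and 0.

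Single libraries lay far from their group by Dixon's test in 7 of 72 tests, where chance gives about 1 in 20, or 3.6. Treated PSUK female replicate 1 had 20.5 M counts, with the next at 16.04 M. Saline female replicate 2 of the agonist experiment had 15.3% mitochondrial counts, with the next at 9.73%. Xist was at 0.474 CPM in gardiquimod male replicate 6, with the next at 0.167 CPM, and at 11.1 CPM in treated PSUK male replicate 1, with the next at 2.90 CPM. The latter library also had the lowest Irf7 of its group, 1.30 CPM with the next at 2.14 CPM. In treated PSUK female replicate 4 Irf7 was at 6.73 CPM, with the next at 2.16 CPM. Wdfy1 was at 29.2 CPM in saline male replicate 5 of the agonist experiment, with the next at 13.7 CPM.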

How the results depend on the processing

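The covariates for Ttr, Pdgfra and the mitochondrial share, the fits without libraries of low mitochondrial share or both female KO libraries numbered 1, and the block within female KO cultures were chosen only after the results were seen.

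Under relative log expression scaling and the replicate block every count of called genes stayed within 1.5 times its value, and so did the myelin counts of male WT, female WT and male KO cultures under every alternative run. Among genes named by the rule no called direction reversed under any fixed alternative or with any library left out. Scaling by relative log expression kept 1419 of 1432 named values on their side of the threshold, DESeq2 1336 of 1391, quality-weighted limma 1343 of 1432, no low-count filter 1351 of 1432, a fit of only the groups compared 1198 of 1286, and the block 1142 of 1161. A fit of only the groups compared was not run where a comparison uses all groups of its experiment.

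Where counts moved by more than 1.5 times the cause was not tested, except that a fit of only the groups compared uses fewer libraries and a stricter filter tests fewer genes. With DESeq2 the counts were 254 for gardiquimod in males (38 in edgeR), 14 in females (4), 153 for its sex difference (1) and 124 for saline females against males (74). For the inhibitor DESeq2 called 202 genes in males (18), 173 in females (15), 6 on average (2), 1631 for the sex difference (413) and 46 for control females against males (11). Its directions were 176 higher and 237 lower for the male genotype difference of the myelin response (114 and 257), and 111 and 91 for the inhibitor in males (6 and 12). Quality-weighted limma called 65, 7 and 11 genes for gardiquimod in males, in females and for the sex difference, 1031 for female against male WT DMSO microglia (536), and 50, 4459, 6, 4732 and 197 for the inhibitor in males, in females, on average, for the sex difference and for control females against males. With no low-count filter the female gardiquimod count was 1, its sex difference 9 and the inhibitor's sex difference 273. With the filter at 5 CPM gardiquimod called 59 genes in males, 24 on average (37) and 5 for the sex difference, female against male WT DMSO microglia 350, and the inhibitor on average 1. With only the groups compared the counts were 19 for gardiquimod in males, 647 for female against male WT myelin microglia (389), 329 and 0 for the inhibitor in males and females, and 5 for PSUK control females against males. That 0 is from edgeR, beside 173 genes in DESeq2, 4459 in limma and 1982 with an unadjusted p under 0.05. Age as a covariate left 8 genes for the inhibitor in females, and males of the age of the male controls alone left 1 gene in males.

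With the Ttr level as a covariate gardiquimod called 3 genes in males and 2 for the sex difference, and the inhibitor 8 in males, 0 in females, 0 on average, 1 for the sex difference and 5 for control females against males. With the mitochondrial share as a covariate gardiquimod called 15 genes in males, 0 in females and 0 for the sex difference, and the inhibitor 89 in males, 1081 in females, 4 on average, 1729 for the sex difference and 145 for controls of the sexes. These counts of 0 are from edgeR, where the unadjusted p was under 0.05 for 1044 genes for gardiquimod in females, 2796 for its sex difference and 625 for the inhibitor on average without the covariates. Without the 4 libraries under 6% mitochondrial counts (PSUK female control 1, male control 3, treated females 1 and 2) the inhibitor called 7 genes in males, 1 in females, 86 for the sex difference and 5 for controls of the sexes. With Ttr and Pdgfra levels as covariates myelin called 2268 genes in female KO cultures, KO against WT 477, 872 and 329 in male DMSO, female DMSO and male myelin cultures, the genotype difference of the female myelin response 40, female against male WT 19 with DMSO and 14 with myelin, and the sex difference of the genotype effect 49.

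The Ttr and Pdgfra covariates also reversed 16 named values, all of which then missed the threshold. Pdgfra, a covariate itself and so near 0 by design, went from -0.95 to 0.035 with myelin in female KO cultures, from -1.02 to 0.020 in male KO against WT with myelin and from -0.92 to 0.041 in female against male DMSO cultures. In male KO against WT with DMSO, Col8a1 went from -3.58 to 0.26, Enpp2 from -3.25 to 0.65, Igfbp2 from -3.15 to 0.30 and Vat1l from -2.65 to 0.88. With myelin, Sulf1 went from -4.09 to 0.53, Col8a1 from -3.43 to 0.32, Enpp2 from -3.37 to 0.41 and Foxj1 from -2.07 to 0.17. In female against male DMSO cultures Scd2 went from -0.15 to 0.0097 and Slc4a4 from -2.58 to 0.043, and for the sex difference of the genotype effect Igfbp2 went from 3.68 to -0.29, Atp1b1 from 3.12 to -0.32 and Wwc1 from 2.76 to -0.30.

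Gene lists were called 276 times with the preset correlation, 53 times with an estimated one, 210 times by fry for a common direction, 291 times by fry for either direction and 280 times with the block. Across genes of at least 5 CPM, Pearson's r was 0.942 and 0.912 between the sexes for myelin in WT and KO, 0.453 and 0.438 for KO against WT with DMSO and myelin, -0.0934 for gardiquimod (-0.0414 over all genes), -0.567 for the inhibitor, and 0.900 and 0.915 between WT and KO for myelin in males and females.

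Leaving out 1 library at a time gave 7 to 329 genes for gardiquimod in males, 0 to 10 in females, 29 to 44 on average, 1 to 35 for its sex difference and 47 to 84 for saline females against males. For myelin it gave 5034 to 5164 genes in male WT, 5180 to 5312 in female WT, 4905 to 5163 in male KO and 5276 to 5579 in female KO cultures. For KO against WT it gave 2304 to 2587 in male DMSO, 1200 to 1383 in female DMSO, 2328 to 2745 in male myelin and 767 to 948 in female myelin cultures. The ranges were 270 to 347 and 73 to 156 for the genotype difference of the myelin response in males and females, 281 to 486 and 213 to 298 for female against male WT with DMSO and myelin, 3 to 6 for the sex difference of the myelin response and 625 to 1326 for that of the genotype effect. For the inhibitor they were 1 to 18 in males, 0 to 93 in females, 1 to 4 on average, 25 to 2500 for the sex difference and 6 to 23 for controls of the sexes. With 3 libraries in a group each such fit leaves 2, whose spread was pooled with that of the other groups.

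For gardiquimod in males the count was 7, 150, 329, 18, 74 and 9 without saline replicate 1, 2, 3, 4, 5 or 6, and 19, 213, 10 and 18 without gardiquimod replicate 2, 4, 5 or 7. In females edgeR called 0 genes without gardiquimod replicate 2 or saline replicate 1, 2, 5 or 7, where all libraries gave 14 in DESeq2, 7 in limma and 1044 at an unadjusted p under 0.05. That count was 2 without gardiquimod replicate 4, 5, 6 or 7 or saline replicate 3, and 10 without saline replicate 4. The sex difference of this response had 4, 6 and 17 genes without male saline replicate 7, 3 or 2, 7 without male gardiquimod replicate 3, 2, 8 and 13 without female saline replicate 4, 2 or 7, and 2 and 35 without female gardiquimod replicate 3 or 5. Saline females against males had 47 without male saline replicate 1. For the inhibitor in males the count was 5 and 1 without control replicate 2 or 3, and 4, 1, 7, 1, 9 and 1 without inhibitor replicate 1, 2, 3, 4, 5 or 6. In females it was 0 without control replicate 1 or 3 (edgeR, with the counts above for all libraries), 38 without control replicate 2, and 6, 93, 7 and 7 without inhibitor replicate 2, 3, 4 or 5. On average it was 1 without female control replicate 3, treated female replicate 4 or male control replicate 1 or 2, and 4 without treated female replicate 1. The sex difference had 1512, 156 and 25 genes without female control replicate 1, 2 or 3, 127 and 34 without male control replicate 2 or 3, 119, 2500 and 233 without treated female replicate 1, 3 or 4, and 119, 138, 262 and 139 without treated male replicate 2, 3, 4 or 6. PSUK control females against males had 6 genes without male control replicate 2 or 3, 7 without female control replicate 3 and 23 without female control replicate 2.

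Female against male WT DMSO cultures gave 337 and 281 genes without female replicate 2 or 3 and 297 and 329 without male replicate 1 or 2, and WT myelin cultures 213 and 238 without female replicate 1 or 3 and 233 without male replicate 2. The sex difference of the myelin response gave 3 genes without female WT myelin replicate 1 or male WT myelin replicate 1 or 2. The female genotype difference of the myelin response gave 73 and 84 without WT myelin replicate 1 or 3 and 75 without WT DMSO replicate 1, and the sex difference of the genotype effect gave 625 without female KO myelin replicate 1. The replicate block within female KO cultures gave 5754 genes beside 5959. In the hippocampus Tlr7 averaged 2.06 to 3.29 CPM and the simulated inhibitor comparison recovered 24% of genes changed 1.5-fold.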

Other observations

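The glucocorticoid, circadian, heat shock, mitochondrially encoded and pituitary lists and the tests on the region around Tlr7 and on Ide were chosen only after the results were seen.

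In saline females against saline males, 12 of 24 glucocorticoid response genes were higher, with a median of 0.55, and 4 of 18 circadian clock output genes, with a median of 0.15. These lists were written after called genes of this comparison had been seen, so no p-value is given for them in it. The 5 pituitary hormone genes had a median of 1.13. Their list was called by camera at the preset correlation (adjusted p = 0.0212) and not with an estimated one (adjusted p = 0.286). Mitochondrially encoded genes were higher in KO microglia except in male DMSO cultures. Of 12 genes, 0, 4, 8 and 8 were called in male DMSO, female DMSO, male myelin and female myelin cultures, with medians of 0.04, 0.21, 0.30 and 0.44. A call of the list held with an estimated correlation in female myelin cultures alone (adjusted p = 0.0495). Of 20 heat shock genes, 3 fell with the inhibitor in males and 5 had a higher log2 response in females than in males. The list was called by camera at the preset correlation (adjusted p = 1.31e-09 and 1.31e-09) and not with an estimated one (adjusted p = 0.200 and 0.200). Of 25 glucocorticoid response genes, 4 fell in males and 6 had a higher log2 response in females. This list too was called by camera at the preset correlation (adjusted p = 0.00532 and 0.0114) and not with an estimated one (adjusted p = 0.542 and 0.597). The pituitary, mitochondrially encoded, heat shock and glucocorticoid lists were also written after the data had been seen. Their p-values in this paragraph are therefore no independent support.

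Lists of other cell types were compared between genotypes. In male KO against WT cultures, 8 and 7 of 19 astrocyte genes and 5 and 6 of 8 pericyte, smooth muscle and fibroblast genes were lower with DMSO and myelin, at medians of -0.99 and -1.08 and of -1.88 and -2.09, without a call of either list (adjusted p = 0.252, 0.185, 0.370 and 0.339 with an estimated correlation). Border-associated macrophage genes were lower in female KO cultures, 4 of 10 with DMSO and 4 with myelin (adjusted p = 0.0444 and 0.0320 with an estimated correlation). The complement list had a call with an estimated correlation in the sex difference of the myelin response, at a median of -0.12 (adjusted p = 0.0320). The neuron, endothelial, peripheral immune, homeostatic, NF-kB, immediate early, MHC class II and unfolded protein response lists had no call with an estimated correlation in any of the 24 comparisons. The erythroid list, tested in hippocampus alone, had none either, and its median was 0.27 and 0.59 with gardiquimod in males and females. Of 4 Y-linked genes, all were lower in females in each comparison of the sexes, and 3 were higher in female KO than in female WT myelin cultures. Of 10 X-linked female-biased genes, 7, 5, 6 and 3 were higher in females in saline hippocampus, WT DMSO microglia, WT myelin microglia and PSUK controls.

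Genes called in the same direction in all 4 KO comparisons numbered 207 higher and 136 lower, Tlr7 included. Within 10 Mb of Tlr7, 5 of the other 46 tested genes were such genes (10.9%), against 337 of 14421 elsewhere (2.34%), with a one-sided Fisher's exact p of 0.00444. These were G530011O06Rik, Gm15726, Mid1, Car5b and Tlr8, the first 2 of which lie inside Mid1. With overlapping genes counted as 1 locus, 3 of 38 loci near Tlr7 and 337 of 12254 elsewhere held such genes (one-sided Fisher's exact p = 0.0870), so sequence carried along with the knockout allele stays open, with too few loci to decide. Wdfy1 lies on another chromosome, and its higher level in KO was not tested further.

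Ide, an insulin-degrading enzyme gene, varied widely among female hippocampi of the agonist experiment, from 39.8 to 61.9 CPM with saline and from 34.3 to 78.1 CPM with gardiquimod, while male libraries held 71.2 to 85.5 CPM. A copy-number allele that spans Ide and its neighbour Fgfbp3 was tested and stays open, since of the genes between them Btaf1 followed Ide (r = 0.875) and Cpeb3 (0.191) and March5 (-0.294) did not. Fgfbp3 followed Ide over the 14 female libraries with group means removed, at a Pearson's r of 0.732 (permutation p = 0.00337) and a Spearman's rho of 0.618 (permutation p = 0.0213), the only relation for which p-values were computed. Without the 2 libraries farthest from the median of Ide, r was 0.559. The other 17 genes within 1 Mb had a median r of 0.00436, although Myof had 0.6247, Pcgf5 0.508 and Cyp26a1 -0.586, which were singled out after their values were seen.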
